A study of Dorcoceras hygrometricum with 9 samples.

How the data were processed

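Transcript abundance was measured in leaf tissue of 9 samples of Boea hygrometrica in 3 water states (hydrated, 70% RWC and 10% RWC) with 3 samples each. Samples titled HD were taken as the hydrated state named in the series' design text, which also calls the samples of a state biological replicates. Per the labels' protocols, potted plants were dried, RNA was extracted with Trizol and libraries followed standard Illumina protocols. How many plants stand behind a sample is not given in the sources used here, nor are the aligner, the assembly version, the counting tool, read filters or strandedness.

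Per the file headers, the authors deposited for each sample the number of reads aligned uniquely to each gene, and these counts are whole numbers that sum to the total stated in the header in 9 of 9 files. Genes with 0 reads are left out of a sample's file and were set to 0. Each row also gives, per the file headers, the percent of the gene covered by reads, which was used for a check of coverage breadth alone. The authors' deposited table of their comparisons against hydrated leaves holds 15319 genes. Per the file headers it gives mean normalized read numbers per group (a signal value, not counts), a fold change as a ratio, its log2 value, a p-value and an adjusted p-value, and the tool behind them is not given in the sources used here. Among its rows, 470 of the 70% RWC comparison and 167 of the 10% RWC comparison hold zeros alone and were left out. A group mean stands at 0.001 in 1663 and 2667 rows, of which 1167 and 1537 have reads in all 3 libraries of that group (up to 21 reads), so fold changes of such rows were not used. Over the other genes the deposited log2 fold changes and those computed here had r = 0.99999 across 13156 and 12448 genes, which are not independent replicates. The median difference was -0.01 at 70% RWC and -0.15 at 10% RWC. The deposited table called 122 and 236 tested genes that were not called here, and 1056 and 856 genes of the table were called here alone.

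Counts were read as deposited. Gene positions and best-match descriptions are those of the authors' files, on scaffolds of an assembly whose version is not given in the sources used here. Gene models held no untranslated regions (100% of lengths are multiples of 3, median coding length 945 bases). Of the genes with a read, 18201 had a database match and 10080 an informative description. A gene's name here is that of its best match, so members of 1 family can share a name, and reads that align equally well to near-identical copies were not counted by the authors' use of unique reads. Values of LEA, ELIP, Rubisco, histone, tubulin and other multigene families are uncertain to that extent. No named gene overlaps another gene model. Without a stated use of strand, reads from antisense transcription cannot be told apart.

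Tests were run in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr (14585 genes kept), a robust quasi-likelihood fit of all 9 libraries with 1 mean per state and no block, and Benjamini-Hochberg adjusted p under 0.05. Prior count for log2 CPM was 2. The SE of a log2 fold change is its size divided by the square root of F. For a gene with 0 reads in a group, the fold is a lower bound against 3 counts over the group's summed libraries, and with 1 to 3 reads the ratio of reads carries an exact 95% binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over lists with at least 5 tested members. With a correlation estimated from the residuals, 7, 6 and 0 lists were called at 70% and 10% RWC against hydrated leaves and at 10% against 70% RWC, beside 18, 18 and 8. Gene ontology terms of 10 to 500 tested genes were tested in the same way.

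The design, the tests, 33 gene lists (search words for descriptions), the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, per comparison, the 6 largest called increases and the 6 largest called decreases among genes with an informative description, non-overlapping groups and at least 20 CPM in the higher group. From each list it takes up to 2 called members with the highest mean CPM and at least a 2-fold change, and it gave 136 genes. Genes named outside it are said to be chosen after their values were seen. Descriptions brought unrelated members into some lists, such as a potassium efflux and a phloem protein among LEA proteins, or vesicle proteins among AP2/ERF factors. Counts without them were added after the values were seen and stand beside a list where a call or the sign of the median changes, and beside some others.

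Counts were simulated with the hydrated means and the library sizes of all 9 libraries, in 10 draws of 13825 to 13852 genes each. In each draw 200 genes were changed at 10% RWC. Against hydrated leaves the test recovered 64.5% of genes changed 1.5-fold (432 of 670), 92.2% at 2-fold (618 of 670) and 99.7% at 4-fold (658 of 660). False calls averaged 8.23% of calls (6.01% to 11.4% over draws), above the nominal rate, while 4.75% of unchanged genes had an unadjusted p under 0.05.

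Replicates were compared first. Replicates 2 and 3 of a state differed by a chi-square per gene of 1.27 to 1.39, little more than sampling noise, and replicate 1 differed from them by 5.01 to 8.60. As the labels call them biological replicates and no pair agreed within sampling noise, 9 libraries were counted as 9 samples. Replicates 2 and 3 may still not be independent, and then SDs, n = 3 and p-values overstate the precision. Replicate numbers come from the sample titles. Deviations from the group means of same-numbered libraries correlated across 7713 genes at 0.476 to 0.544 for number 1 and 0.213 to 0.313 for numbers 2 and 3, all above 0.1. The number was therefore used as a block in an alternative fit, while the main fit has none. Replicates 2 and 3 of different states correlated alike (0.151 to 0.381), and 1 against the others at -0.465 to -0.262. These values set replicate 1 apart and do not show that numbers 2 or 3 pair the samples. Alternatives were RLE scaling, total counts, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, fits of the 2 compared states, the replicate block, a 2-fold minimum, thinning to the smallest library and leaving out each library. Added after the libraries had been compared were replicates 2 and 3 alone, replicates 2 and 3 summed, replicate 1 as a batch term, and lists without unrelated members. Alternatives planned for RPKM values were not needed, as the files hold counts. A check of GC content was not run, for lack of a genome sequence here.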

Results

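Transcript abundance was measured by RNA sequencing in leaves of Boea hygrometrica (Dorcoceras hygrometricum in the labels), a resurrection plant whose leaves survive drying and recover when watered. Potted plants were sampled in 3 water states, which are hydrated leaves, leaves dried to 70% relative water content (RWC, leaf water relative to the fully hydrated leaf) and leaves dried to 10% RWC. Each state had 3 libraries, described as biological replicates in the series' design text. A read was found for 24182 genes in at least 1 library and for 14410 genes in all 9 libraries. The 14585 genes that entered the tests held from 6654601 reads in hydrated replicate 3 to 7423965 reads in hydrated replicate 1, at least 99.8% of each library. Genes with a read numbered 18467 ± 84.9 (SD, n = 3) per hydrated library, 18088 ± 119.7 at 70% RWC and 18258 ± 67.5 at 10% RWC. Gene values below are mean CPM (read counts scaled to a common library size) ± SD over the 3 libraries of a group, with the wetter state first. They are relative to the other transcripts of a library, and amounts per leaf were not measured. Log2 fold changes are given ± SE, and folds against groups with 0 reads are lower bounds against a floor of 3 reads over the group. Where a group had 1 to 3 reads, the ratio of reads is given with its 95% counting interval. Adjusted p values of genes come from edgeR's quasi-likelihood test and those of lists from camera, which compares a list with the other genes.

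The 3 water states separated on the first principal components, which held 72.6% and 23.8% of the variance of log2 CPM. The third component, with 1.16% of the variance, set replicate 1 of each state apart from replicates 2 and 3. Between replicate 1 and the other replicates 2970 genes differed over the 3 states (1415 higher and 1555 lower in replicate 1), of which 62 differed at least 2-fold. Members of the photosystem and light-harvesting list were among them, with 17 of 30 lower and 2 higher in replicate 1 (camera adjusted p = 1.43e-06). Within a state, replicates 2 and 3 differed by little more than sampling noise (chi-square per gene of 1.27 to 1.39, against 5.01 to 8.60 for replicate 1 with either). The sources used here do not say whether they came from separate plants. If they did not, the SDs and p-values below, and all values from replicates 2 and 3 alone, measure a spread that may be technical, and n is 2 rather than 3. Summed as 1 sample per state, they gave 9608 genes at 70% RWC, 12103 at 10% RWC and 10736 between 70% and 10% RWC. Every state held 1 replicate 1 library, so each comparison is also given for replicates 2 and 3 alone, a setting chosen after the libraries had been compared.

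**Figure D1:**
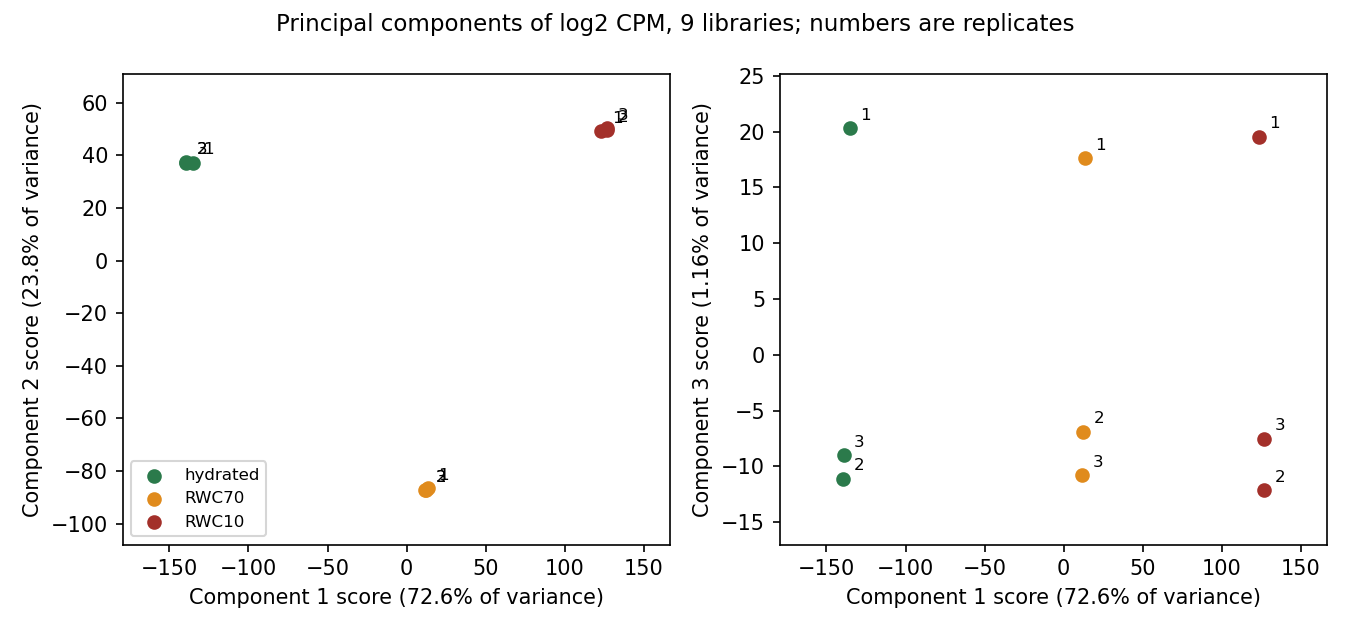
Scores of the 9 libraries on principal components of log2 CPM, with components 1 and 2 on the left and components 1 and 3 on the right, colored by water state and numbered by replicate. The states separate on components 1 and 2 (72.6% and 23.8% of the variance), and replicate 1 of each state lies above replicates 2 and 3 on component 3 (1.16%).

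The first comparison asked which transcripts differed between hydrated leaves and leaves at moderate dehydration, 70% RWC. Late embryogenesis abundant (LEA) proteins are hydrophilic proteins that accumulate in drying seeds and in water-stressed tissue. Tested members of the LEA list grew from 0.162 ± 0.00979% to 6.72 ± 0.794% of all CPM (n = 3). Genes of the family whose description lacks the list's search words are not in that share. Of the LEA list, 25 of 27 tested members were higher and 1 was lower. Early light-induced proteins (ELIPs), chlorophyll-binding proteins made under light stress, were higher for 12 of 13 members. Photosystem and light-harvesting transcripts fell from 5.92 ± 0.749% to 0.904 ± 0.0798% of all CPM, with 23 of 30 members lower. The Calvin cycle list fell from 5.62 ± 0.7003% to 0.715 ± 0.0705%, with 14 of 23 members lower.

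In total 10284 of 14585 genes differed between 70% RWC and hydrated leaves by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5043 higher and 5241 lower. At least 2-fold changes were found for 5189 genes, 2205 higher and 2984 lower. Lower genes outnumbered higher ones under each scaling, with 4720 higher and 5507 lower under RLE scaling and 4380 and 5780 with total counts. With replicates 2 and 3 alone 10582 genes were called. Replicate 1 has 1 library per state and allows no test of its own. Its log2 fold changes and those of replicates 2 and 3 had r = 0.971 across all 14585 genes, which are not independent replicates. The authors' deposited table called 9781 genes in this comparison, of which 9310 were tested here, and 9188 of these were called here in the same direction.

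The largest called increases at 70% RWC, among annotated genes with at least 20 CPM in the higher group and no overlap between groups, were in 3 LEA genes and 3 others. LEA gene Bhs222_060V1.1 went from 0.234 ± 0.167 to 787 ± 190.4 CPM (log2 fold change 11.63 ± 0.52, adjusted p = 3.73e-07). LEA genes Bhs152_034V1.1 (0.999 ± 0.362 to 1732 ± 183 CPM) and Bhs4_093V1.1 (0.787 ± 0.878 to 1267 ± 144 CPM) rose as well. A GDSL esterase gene, Bhs2761_010V1.1, went from 0 reads to 44.99 ± 5.14 CPM, at least 324-fold higher. An anoctamin-like gene, Bhs2050_008V1.1, rose from 0.522 ± 0.654 to 1368 ± 32.9 CPM, and the aldose reductase gene Bhs1189_001V1.1 from 2.02 ± 1.05 to 2811 ± 53.2 CPM. The largest decreases by the same rule included wall proteins and an aquaporin. A proline-rich cell wall protein gene, Bhs6_089V1.1, went from 121 ± 26.3 CPM to 0 reads, at least 829-fold lower. An aquaporin gene, Bhs1906_008V1.1, went from 26.9 ± 5.298 CPM to 0 reads, at least 185-fold lower. An expansin, a wall-loosening protein (Bhs109_026V1.1), fell from 235 ± 33.9 to 0.343 ± 0.474 CPM. An aspartic proteinase gene, Bhs1073_011V1.1, fell from 41.6 ± 4.995 to 0.0491 ± 0.08503 CPM, a read ratio of 0.00116 with a counting interval of 2.93e-05 to 0.00648. A fasciclin-like arabinogalactan protein gene, Bhs4081_002V1.1, fell from 208 ± 45.3 to 0.523 ± 0.2799 CPM, and an ABC transporter gene, Bhs730_024V1.1, from 181 ± 5.35 to 0.718 ± 0.2403 CPM.

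Among protective genes at 70% RWC, the LEA list was called higher by camera (median log2 fold change 6.32, adjusted p = 2.41e-11, and adjusted p = 0.0391 with an estimated correlation). The dehydrin-like gene Dh2 (Bhs1066_009V1.1, scaffold 1066, positions 359475 to 360225, plus strand) rose from 82.8 ± 3.52 to 10833 ± 1553 CPM. LEA gene Bhs267_026V1.1 rose from 9.39 ± 4.25 to 8988 ± 403 CPM. The ELIP list was called higher (median log2 fold change 4.19 with genes at 0 reads set to their bound, adjusted p = 1.60e-05, and adjusted p = 0.0597 with an estimated correlation). ELIP Bhs474_011V1.1 (scaffold 474, positions 478830 to 479586, plus strand) rose from 0.7198 ± 0.654 to 357 ± 8.02 CPM and Bhs11779_003V1.1 from 35.6 ± 2.27 to 648 ± 21.6 CPM. The list of synthesis and signalling of abscisic acid (ABA), a stress hormone, had 32 higher and 9 lower of 48 tested (adjusted p = 1.60e-05, and adjusted p = 0.0391 with an estimated correlation). Its protein phosphatase 2C genes, a family that includes repressors of ABA signalling, rose from 12.3 ± 0.225 to 527 ± 16.5 CPM for Bhs71_001V1.1 and from 0.455 ± 0.178 to 119 ± 8.66 CPM for Bhs862_005V1.1. Heat stress transcription factors had 12 higher and 3 lower of 18 tested (adjusted p = 0.00804, and adjusted p = 0.0596 with an estimated correlation). The A-6b-like factor Bhs3828_002V1.1 rose from 226 ± 25.2 to 632 ± 42.02 CPM and heat shock factor Bhs826_024V1.1 from 17.9 ± 2.28 to 345 ± 10.1 CPM.

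In the chloroplast, the photosystem list was called lower at 70% RWC (median log2 fold change -2.70, adjusted p = 2.28e-06, and adjusted p = 0.1099 with an estimated correlation), and 4 of its 5 higher members were ELIPs matched by their description. Without these ELIPs, the list had 1 higher and 23 lower of 26 tested (adjusted p = 9.36e-10, and adjusted p = 0.0729 with an estimated correlation). In replicate 1, 17 of the 30 members were lower than in replicates 2 and 3 over all states. Lhcb1 (Bhs8864_002V1.1), an antenna protein of photosystem II, fell from 7239 ± 1119 to 2809.9 ± 253 CPM. The oxygen-evolving enhancer gene Bhs2039_003V1.1 fell from 8286 ± 466 to 1208 ± 87.9 CPM. The Calvin cycle list was called lower (adjusted p = 3.29e-04, and adjusted p = 0.0596 with an estimated correlation). Members such as Rubisco-binding chaperonins and methyltransferases had entered by their descriptions, and without them 9 of 9 members were lower (adjusted p = 7.12e-06, and adjusted p = 0.0305 with an estimated correlation). The Rubisco small subunit gene (Bhs5191_005V1.1, scaffold 5191, positions 47733 to 48458, plus strand), part of the CO2-fixing enzyme, fell from 19248 ± 3789 to 2209 ± 454 CPM. Rubisco activase Bhs7545_001V1.1 fell from 16114 ± 2196 to 1228 ± 105 CPM. Chlorophyll synthesis had 1 higher and 8 lower of 9 tested (adjusted p = 1.60e-04, and adjusted p = 0.0391 with an estimated correlation). Its monomethyl ester cyclase gene Bhs32_068V1.1 fell from 2654 ± 8.98 to 363 ± 9.17 CPM and its magnesium chelatase gene Bhs68_009V1.1 from 1837 ± 32.8 to 289 ± 5.36 CPM. Chlorophyll breakdown and senescence had 6 higher and 3 lower of 9 tested (adjusted p = 0.0286, and adjusted p = 0.265 with an estimated correlation). Pheophorbide a oxygenase Bhs1906_004V1.1, a chlorophyll-degrading enzyme, rose from 285 ± 30.3 to 889 ± 46.7 CPM and a senescence-related gene, Bhs7_151V1.1, from 11.9 ± 1.28 to 965 ± 24.8 CPM.

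At 70% RWC, cytosolic ribosomal proteins had 5 higher and 46 lower of 87 tested (adjusted p = 0.00524, and adjusted p = 0.0596 with an estimated correlation), with a median log2 fold change of -0.29. Ribosomal protein S15 (Bhs13_133V1.1) fell from 95.2 ± 4.37 to 46.4 ± 1.72 CPM. An L7-like gene, Bhs2912_005V1.1, rose from 0.845 ± 0.552 to 1.78 ± 0.497 CPM (adjusted p = 0.0382). That call ended under 7 of 21 alternatives, whose adjusted p ranged from 0.00727 to 0.152. They included fits without hydrated replicate 1 (adjusted p = 0.111), without hydrated replicate 2 (adjusted p = 0.147) and without replicate 3 of 70% RWC (adjusted p = 0.152). Organelle ribosomal proteins had 2 higher and 19 lower of 31 tested (adjusted p = 3.29e-04, and adjusted p = 0.0391 with an estimated correlation). Chloroplast S13 (Bhs387_045V1.1) fell from 274 ± 11.4 to 91.3 ± 5.07 CPM and L28 (Bhs1169_002V1.1) from 169 ± 29.5 to 75.5 ± 4.66 CPM. The proteasome, the main protein-degrading complex, had 25 higher and 1 lower of 32 tested (adjusted p = 3.35e-04, and adjusted p = 0.0859 with an estimated correlation). Proteasome activator subunit Bhs12440_002V1.1 rose from 56.8 ± 3.11 to 129 ± 9.56 CPM and beta subunit Bhs13074_002V1.1 from 4.84 ± 0.564 to 10.02 ± 1.27 CPM. Ubiquitin ligases, which mark proteins for degradation, had 113 higher and 50 lower of 218 tested (adjusted p = 0.00571, and adjusted p = 0.0391 with an estimated correlation). The BRE1A-like gene Bhs710_012V1.1 rose from 100.3 ± 12.7 to 440.2 ± 19.6 CPM and the UPL4-like gene Bhs7077_004V1.1 from 131 ± 4.97 to 306 ± 15.2 CPM.

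Cell wall loosening and synthesis at 70% RWC had 13 higher and 55 lower of 82 tested (adjusted p = 9.80e-06, and adjusted p = 0.0186 with an estimated correlation). The named members were among its higher ones, with pectinesterase Bhs1456_002V1.1 going from 21.2 ± 3.22 to 1233 ± 197 CPM and xyloglucan endotransglucosylase XTH5 (Bhs40_123V1.1) from 224 ± 13.4 to 794 ± 16.1 CPM. Aquaporins, water channels, had 1 higher and 7 lower of 8 tested (adjusted p = 0.0218, and adjusted p = 0.288 with an estimated correlation). PIP2.2 (Bhs95_066V1.1) fell from 268 ± 62.5 to 28.2 ± 2.22 CPM and Bhs316_023V1.1 from 171 ± 23.6 to 13.8 ± 0.573 CPM. Actin and tubulin had 9 higher and 16 lower of 30 tested (adjusted p = 0.04297, and adjusted p = 0.0948 with an estimated correlation). The call was lost when replicates 2 and 3 were summed (adjusted p = 0.0560, from 0.0374 to 0.0560 over 15 settings). Without actin-binding and actin-related proteins the list had 1 higher and 11 lower of 14 tested (adjusted p = 4.46e-04, and adjusted p = 0.0305 with an estimated correlation). Actin 1 (Bhs455_002V1.1) fell from 1509 ± 9.83 to 491 ± 4.37 CPM and alpha tubulin Bhs12_047V1.1 from 1450.4 ± 38.8 to 195 ± 10.4 CPM. Phenylpropanoid and flavonoid enzymes had 12 higher and 31 lower of 50 tested (adjusted p = 0.0171, and adjusted p = 0.0596 with an estimated correlation). Phenylalanine ammonia-lyase (Bhs160_034V1.1), the entry enzyme of the pathway, fell from 894 ± 44.5 to 146 ± 11.2 CPM, and a flavanone rhamnosyltransferase gene, Bhs4478_002V1.1, rose from 4.28 ± 0.3996 to 627 ± 36.3 CPM. Cuticle and epidermis markers had 5 higher and 21 lower of 32 tested (adjusted p = 0.00118, and adjusted p = 0.0391 with an estimated correlation). The 3-ketoacyl-CoA synthase Bhs4608_002V1.1, an enzyme type that elongates wax precursors, fell from 478 ± 24.5 to 4.42 ± 0.316 CPM and cutin deficient 2 (Bhs45_098V1.1) from 74.3 ± 9.896 to 26.9 ± 2.25 CPM. Lipid remodelling had 24 higher and 12 lower of 43 tested (adjusted p = 0.0445, and adjusted p = 0.121 with an estimated correlation). The lipid call was lost with the replicate number as a block (adjusted p = 0.0511) and in 10 of 15 settings in all, with adjusted p from 0.0386 to 0.0807. It was lost in replicates 2 and 3 alone (adjusted p = 0.0699) and without hydrated replicate 1 (adjusted p = 0.0589). Without replicates 1, 2 and 3 of 70% RWC the adjusted p was 0.0657, 0.0711 and 0.0603, and without those of 10% RWC it was 0.0651, 0.0680 and 0.0702. Phospholipase D gene Bhs3997_016V1.1 rose from 46.5 ± 4.69 to 496 ± 17.4 CPM and diacylglycerol kinase Bhs5_001V1.1 from 62.5 ± 2.01 to 374 ± 26.2 CPM.

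The other lists were not called as sets at 70% RWC. Small heat shock proteins had 3 higher and 4 lower of 10, adjusted p = 0.918. The named members match larger heat shock proteins by their descriptions, and Bhs29_014V1.1 rose from 47.3 ± 4.67 to 159 ± 4.63 CPM and Bhs3177_005V1.1 from 243 ± 16.97 to 587 ± 18.4 CPM. Without such members the list had 1 higher and 3 lower of 5 tested. Large heat shock proteins and chaperones had 10 higher and 12 lower of 34, adjusted p = 0.897, with a median of -0.13, a mean of 0.00 and a negative set test. HSP90 (Bhs7_048V1.1) fell from 1417 ± 38.5 to 554 ± 19.8 CPM and a luminal-binding protein (Bhs78_025V1.1), a chaperone of the endoplasmic reticulum, from 1216 ± 126 to 564 ± 12.4 CPM. Oleosins and seed storage proteins had 5 higher and 3 lower of 10, adjusted p = 0.197, and 7 of the 10 matched basic globulins or antimicrobial peptides, such as globulin Bhs83_038V1.1 (266 ± 45.5 to 909 ± 153 CPM). In replicate 1, 3 of the 10 were lower and 0 higher than in replicates 2 and 3 (adjusted p = 0.00113). A peroxygenase of the caleosin type, Bhs39_021V1.1, rose from 32.6 ± 0.989998 to 1264 ± 35.97 CPM. Raffinose family and sucrose synthesis had 13 higher and 9 lower of 25, adjusted p = 0.144. Sucrose synthase 2 (Bhs983_003V1.1) rose from 88.3 ± 3.08 to 5508 ± 52.6 CPM and stachyose synthase (Bhs33_062V1.1) from 616 ± 44.9 to 1409 ± 56.9 CPM. Antioxidant enzymes had 15 higher and 16 lower of 47, adjusted p = 0.897, with a median of -0.09, a mean of 0.28 and a positive set test. Monodehydroascorbate reductase Bhs6432_001V1.1 rose from 593 ± 25.4 to 1979.8 ± 64.1 CPM and glutathione peroxidase Bhs4_048V1.1 from 84.96 ± 8.08 to 1911 ± 139.7 CPM. Glutathione S-transferases had 6 higher and 6 lower of 16, adjusted p = 0.769, and their median of 0.06 became -0.04 when libraries were scaled by total counts. GSTU45 (Bhs1067_009V1.1) fell from 58.7 ± 5.48 to 5.81 ± 0.0605 CPM, and Bhs4989_009V1.1 rose from 0.0473 ± 0.0819 to 11.7 ± 0.674 CPM, a read ratio of 253 with a counting interval of 45.002 to 10038.

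NAC factors at 70% RWC had 13 higher and 6 lower of 25, adjusted p = 0.0868, WRKY factors 20 higher and 12 lower of 36, adjusted p = 0.0991, AP2/ERF and DREB factors 23 higher and 15 lower of 52, adjusted p = 0.243 and MYB factors 15 higher and 22 lower of 44, adjusted p = 0.469. WRKY6 (Bhs51_098V1.1) rose from 92.9 ± 5.76 to 436 ± 23.3 CPM and WRKY I (Bhs2527_008V1.1) from 53.1 ± 4.23 to 407 ± 24.1 CPM. NAC gene Bhs574_015V1.1 rose from 28.04 ± 2.39 to 64.03 ± 5.97 CPM, and a NAC78-like gene, Bhs183_066V1.1, fell from 68.6 ± 6.31 to 31.97 ± 3.11 CPM. A dehydration-responsive element binding (DREB) gene, Bhs177_007V1.1, rose from 5.41 ± 0.624 to 116 ± 2.06 CPM and AP2 gene Bhs451_042V1.1 from 14.7 ± 1.74 to 57.5 ± 4.33 CPM. MYB185 (Bhs119_047V1.1) fell from 152 ± 9.41 to 66.3 ± 11.1 CPM, and MYB44 (Bhs1239_024V1.1) rose from 18.3 ± 2.298 to 96.7 ± 12.7 CPM. Histones and cell cycle had 14 higher and 36 lower of 67, adjusted p = 0.0723, and without histone methyltransferases 11 higher and 36 lower of 63 tested (adjusted p = 0.0316, and adjusted p = 0.167 with an estimated correlation). Histone H2B.2 (Bhs120_034V1.1) went from 0.0916 ± 0.0799 to 94.6 ± 8.36 CPM, a read ratio of 1024 with a counting interval of 283 to 8460.4, and histone H2 gene Bhs106_047V1.1 rose from 13.1 ± 2.91 to 43.6 ± 7.66 CPM. Splicing factors had 15 higher and 8 lower of 50, adjusted p = 0.285. A PRP-type helicase gene, Bhs401_030V1.1, rose from 60.2 ± 4.55 to 130.2 ± 5.65 CPM and splicing factor Bhs13_117V1.1 fell from 64.4 ± 5.53 to 25.1 ± 1.29 CPM. Autophagy had 4 higher and 0 lower of 6, adjusted p = 0.0996, with ATG9-like Bhs12_112V1.1 going from 44.7 ± 1.11 to 90.6 ± 1.498 CPM and ATG5-like Bhs4989_007V1.1 from 20.4 ± 0.905 to 44.2 ± 2.11 CPM. Vascular markers had 8 higher and 9 lower of 18, adjusted p = 0.897, with a sucrose transporter (Bhs865_013V1.1, 48.9 ± 3.52 to 1365 ± 66.8 CPM) and a laccase (Bhs649_092V1.1, 50.5 ± 2.27 to 458 ± 50.02 CPM) higher. Guard cell markers numbered 4, too few for a set test, and 1 of them is stomatin-like by its description. Among them MYB60 (Bhs361_026V1.1) fell from 20.4 ± 2.803 to 7.24 ± 1.18 CPM and FAMA (Bhs5_171V1.1) from 5.79 ± 0.843 to 1.72 ± 0.762 CPM. Adjusted over the list alone, counts matched those over all genes in every list except cytosolic ribosomal proteins (3 higher), large heat shock proteins (11 lower), WRKY (21 higher), MYB (16 higher) and cuticle markers (22 lower).

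**Figure D2:**
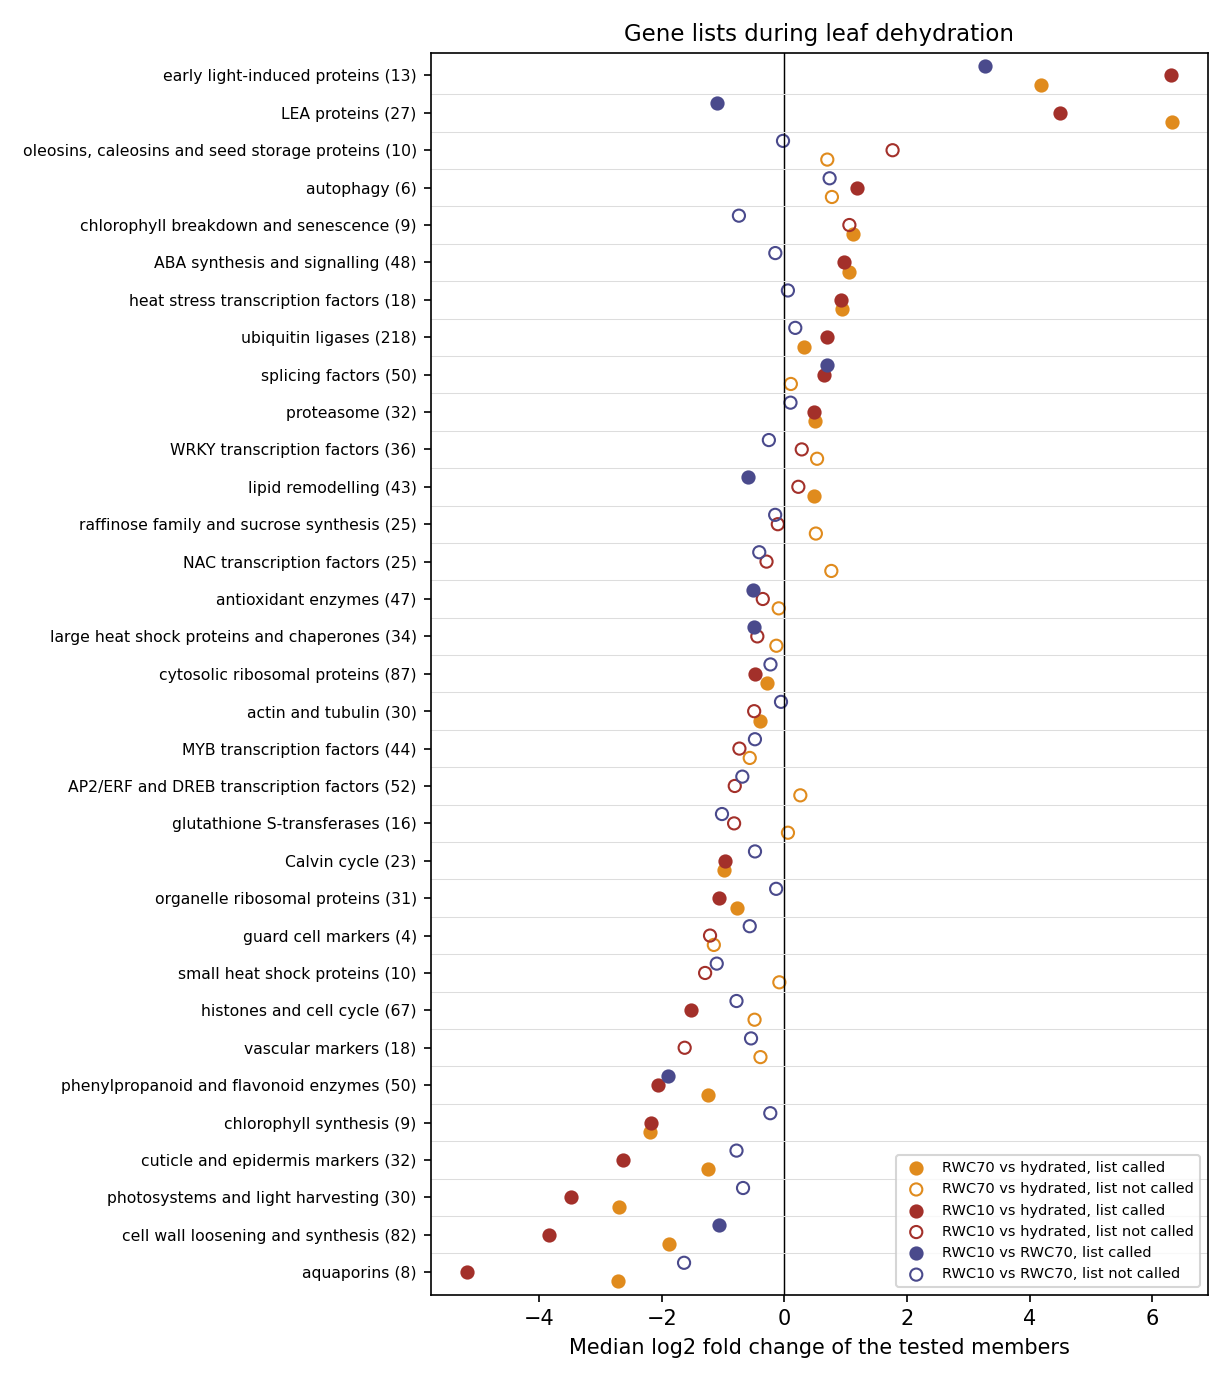
Median log2 fold change of the tested members (number in brackets) of 33 gene lists fixed before the data were examined, for the 3 comparisons, with genes at 0 reads in a group set to their bound. Filled points are lists called by camera with a preset correlation of 0.01, open points lists that were not called. LEA proteins lie at 6.32 and 4.49 against hydrated leaves, and photosystems at -2.70 and -3.47. The medians of glutathione S-transferases at 70% RWC and, between 70% and 10% RWC, of oleosins and of actin and tubulin change sign with total-count scaling.

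The second comparison set desiccated leaves, at 10% RWC, against hydrated leaves. ELIPs were higher for 13 of 13 members, and ELIP Bhs474_011V1.1 rose from 0.7198 ± 0.654 to 3244 ± 83.5 CPM (log2 fold change 12.07 ± 0.21, adjusted p = 2.44e-15). The LEA list made up 3.42 ± 0.386% of all CPM, with 22 of 27 members higher than in hydrated leaves and 3 lower. The LEA group 3-like gene Bhs152_037V1.1 (scaffold 152, positions 236088 to 236650, plus strand) rose from 2.12 ± 2.05 to 9536 ± 984 CPM. The Rubisco small subunit gene fell from 19248 ± 3789 to 232 ± 33.9 CPM (log2 fold change -6.38 ± 0.26), and photosystem transcripts stood at 0.516 ± 0.0435% of all CPM. Cell wall genes were lower for 61 of 82 members.

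In total 12235 of 14585 genes differed at 10% RWC by edgeR's quasi-likelihood test, 6177 higher and 6058 lower, and 8116 of them differed at least 2-fold (3784 higher, 4332 lower). TMM and RLE scaling assume that most genes are unchanged, while 83.9% were called here, so the balance of directions rests on the scaling. Which direction held more genes depended on the setting, with 5912 higher and 6355 lower under RLE scaling, 6077 and 6137 with total counts and 6000 and 6627 by DESeq2. Lower genes were also more numerous without a filter (6353 and 7293), in a fit of the 2 states (5719 and 6358) and without replicate 1 of 70% RWC (5886 and 6607). Replicates 2 and 3 alone gave 12457 genes, and their log2 fold changes and those of replicate 1 had r = 0.983 across all 14585 genes. The authors' deposited table called 12198 genes, of which 11591 were tested here, and 11355 of these were called here in the same direction.

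The largest increases at 10% RWC, besides ELIP Bhs474_011V1.1 and LEA gene Bhs152_037V1.1, included another ELIP, Bhs2978_003V1.1, which went from 0 reads to 301 ± 29.2 CPM, at least 2173-fold higher. LEA gene Bhs222_060V1.1 rose from 0.234 ± 0.167 to 883 ± 201 CPM. A thaumatin-like gene, Bhs4423_002V1.1, went from 0 reads to 61.9 ± 14.9 CPM, at least 446-fold higher, and a vacuolar cation/proton exchanger, Bhs370_036V1.1, from 0 reads to 40.8 ± 1.59 CPM, at least 295-fold higher. Among the largest decreases, the proline-rich cell wall gene Bhs6_089V1.1 went from 121 ± 26.3 CPM to 0 reads, at least 878-fold lower. A fasciclin-like arabinogalactan protein gene, Bhs3967_008V1.1, went from 116 ± 13.9 CPM to 0 reads, at least 847-fold lower, and aquaporin Bhs1906_008V1.1 from 26.9 ± 5.298 CPM to 0 reads, at least 196-fold lower. Decreases to 0 reads were ranked by a fitted fold as well, and their place is uncertain. A phosphate-induced protein gene, Bhs771_074V1.1, fell from 176 ± 28.6 to 0.0444 ± 0.0769 CPM, a read ratio of 2.60e-04 with a counting interval of 6.58e-06 to 0.00145. Pectinesterase Bhs1115_028V1.1 fell from 246 ± 25.9 to 0.0888 ± 0.154 CPM, a read ratio of 3.71e-04 with a counting interval of 4.50e-05 to 0.00134, and peroxidase 21 (Bhs451_033V1.1) from 103 ± 3.87 to 0.0444 ± 0.0769 CPM, a read ratio of 4.39e-04 with a counting interval of 1.11e-05 to 0.00245.

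Among protective genes at 10% RWC, the LEA list was called higher (median log2 fold change 4.49, adjusted p = 2.30e-05, and adjusted p = 0.129 with an estimated correlation). Dh2 rose from 82.8 ± 3.52 to 8156 ± 1059.7 CPM and LEA gene Bhs267_026V1.1 from 9.39 ± 4.25 to 3556 ± 78.3 CPM. ELIPs were called higher (median log2 fold change 6.30 with genes at 0 reads at their bound, adjusted p = 2.11e-05, and adjusted p = 0.0805 with an estimated correlation), and Bhs11779_003V1.1 rose from 35.6 ± 2.27 to 393 ± 15.03 CPM. The ABA list had 35 higher and 9 lower of 48 tested (adjusted p = 0.00204, and adjusted p = 0.0985 with an estimated correlation). Phosphatase 2C gene Bhs71_001V1.1 rose from 12.3 ± 0.225 to 81.9 ± 1.36 CPM, and zeaxanthin epoxidase (Bhs464_019V1.1), which acts early in ABA synthesis, fell from 576 ± 11.6 to 268 ± 2.24 CPM. Heat stress transcription factors had 15 higher and 3 lower of 18 tested (adjusted p = 0.0174, and adjusted p = 0.0985 with an estimated correlation). Bhs826_024V1.1 rose from 17.9 ± 2.28 to 203 ± 7.22 CPM and the A-6b-like factor fell from 226 ± 25.2 to 77.1 ± 11.8 CPM. Autophagy, the bulk degradation of cell contents, had 5 higher and 0 lower of 6 tested (adjusted p = 0.0445, and adjusted p = 0.171 with an estimated correlation), a call that changed in 4 of 15 settings, with adjusted p from 0.0382 to 0.0566. It was lost with the replicate block (adjusted p = 0.0525), with replicate 1 as a batch (adjusted p = 0.0523), in replicates 2 and 3 alone (adjusted p = 0.0566) and without hydrated replicate 3 (adjusted p = 0.0516). ATG9-like Bhs12_112V1.1 rose from 44.7 ± 1.11 to 275 ± 7.33 CPM and ATG5-like Bhs4989_007V1.1 from 20.4 ± 0.905 to 108 ± 3.004 CPM.

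At 10% RWC, photosystems had 6 higher and 23 lower of 30 tested (adjusted p = 4.91e-05, and adjusted p = 0.165 with an estimated correlation), and Lhcb1 fell from 7239 ± 1119 to 1090.3 ± 143 CPM and the oxygen-evolving enhancer from 8286 ± 466 to 1374 ± 82.4 CPM. Calvin cycle had 6 higher and 16 lower of 23 tested (adjusted p = 0.005396, and adjusted p = 0.134 with an estimated correlation), and Rubisco activase Bhs7545_001V1.1 fell from 16114 ± 2196 to 449 ± 37.2 CPM. Without chaperonins, methyltransferases and similar matches, 9 of 9 members were lower (adjusted p = 2.08e-05, and adjusted p = 0.0343 with an estimated correlation). Chlorophyll synthesis had 0 higher and 9 lower of 9 tested (adjusted p = 1.69e-04, and adjusted p = 0.0396 with an estimated correlation). The monomethyl ester cyclase fell from 2654 ± 8.98 to 548 ± 14.8 CPM and magnesium chelatase from 1837 ± 32.8 to 52.6 ± 5.38 CPM. Organelle ribosomal proteins had 7 higher and 20 lower of 31 tested (adjusted p = 0.00903, and adjusted p = 0.0764 with an estimated correlation). Chloroplast S1 (Bhs2537_002V1.1) fell from 321 ± 5.22 to 136 ± 11.4 CPM and S13 from 274 ± 11.4 to 102 ± 3.05 CPM. Cytosolic ribosomal proteins had 11 higher and 58 lower of 87 tested (adjusted p = 0.00138, and adjusted p = 0.0454 with an estimated correlation). P0 (Bhs4929_001V1.1) fell from 363 ± 21.9 to 179 ± 6.41 CPM and an L7-like gene, Bhs33_044V1.1, rose from 79.9 ± 9.14 to 312 ± 40.2 CPM.

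Ubiquitin ligases at 10% RWC had 129 higher and 57 lower of 218 tested (adjusted p = 0.00204, and adjusted p = 0.0369 with an estimated correlation). BRE1A-like Bhs710_012V1.1 rose from 100.3 ± 12.7 to 1322 ± 89.5 CPM and UPL4-like Bhs7077_004V1.1 from 131 ± 4.97 to 1386 ± 23.2 CPM. The proteasome had 23 higher and 4 lower of 32 tested (adjusted p = 0.00613, and adjusted p = 0.165 with an estimated correlation). Regulatory subunit RPN1 (Bhs703_001V1.1) rose from 129 ± 2.44 to 297 ± 10.5 CPM and activator subunit Bhs12440_002V1.1 from 56.8 ± 3.11 to 137 ± 5.23 CPM. Splicing factors had 36 higher and 9 lower of 50 tested (adjusted p = 0.00119, and adjusted p = 0.155 with an estimated correlation). The PRP8-like gene Bhs152_009V1.1, a core protein of the spliceosome, rose from 313 ± 13.01 to 1099.6 ± 18.99 CPM and the U5 helicase gene Bhs200_062V1.1 from 258 ± 11.97 to 1105 ± 39.7 CPM.

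Cell wall genes were called lower at 10% RWC (median log2 fold change -3.84, adjusted p = 2.11e-05, and adjusted p = 0.0202 with an estimated correlation). A xyloglucan endotransglycosylase (XET) gene, Bhs2041_015V1.1 (scaffold 2041, positions 107279 to 108303, minus strand), fell from 919 ± 52.96 to 1.398 ± 1.202 CPM, and pectinesterase Bhs1456_002V1.1 rose from 21.2 ± 3.22 to 52.7 ± 9.48 CPM. Aquaporins had 2 higher and 6 lower of 8 tested (median log2 fold change -5.18 at the bound, adjusted p = 0.0353, and adjusted p = 0.34004 with an estimated correlation). Bhs3276_001V1.1 fell from 595 ± 68.7 to 134 ± 17.97 CPM and PIP2.2 from 268 ± 62.5 to 0.269 ± 0.351 CPM. Histones and cell cycle had 15 higher and 41 lower of 67 tested (adjusted p = 0.0242, and adjusted p = 0.144 with an estimated correlation). Histone H1 (Bhs7477_002V1.1) fell from 187 ± 4.56 to 26.4 ± 1.4004 CPM, and a cyclin-dependent kinase G-2-like gene, Bhs828_018V1.1, rose from 101.3 ± 8.304 to 510.0 ± 17.7 CPM. Phenylpropanoid enzymes had 8 higher and 39 lower of 50 tested (adjusted p = 1.69e-04, and adjusted p = 0.0358 with an estimated correlation). Phenylalanine ammonia-lyase fell from 894 ± 44.5 to 7.59 ± 1.97 CPM and leucoanthocyanidin dioxygenase (Bhs693_021V1.1) from 455 ± 24.9 to 212 ± 22.6 CPM. Cuticle and epidermis markers had 4 higher and 21 lower of 32 tested (adjusted p = 0.00138, and adjusted p = 0.0425 with an estimated correlation). 3-ketoacyl-CoA synthases Bhs4608_002V1.1 fell from 478 ± 24.5 to 0.356 ± 0.504 CPM and Bhs4383_003V1.1 from 90.1 ± 14.7 to 8.23 ± 2.35 CPM.

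**Figure D3:**
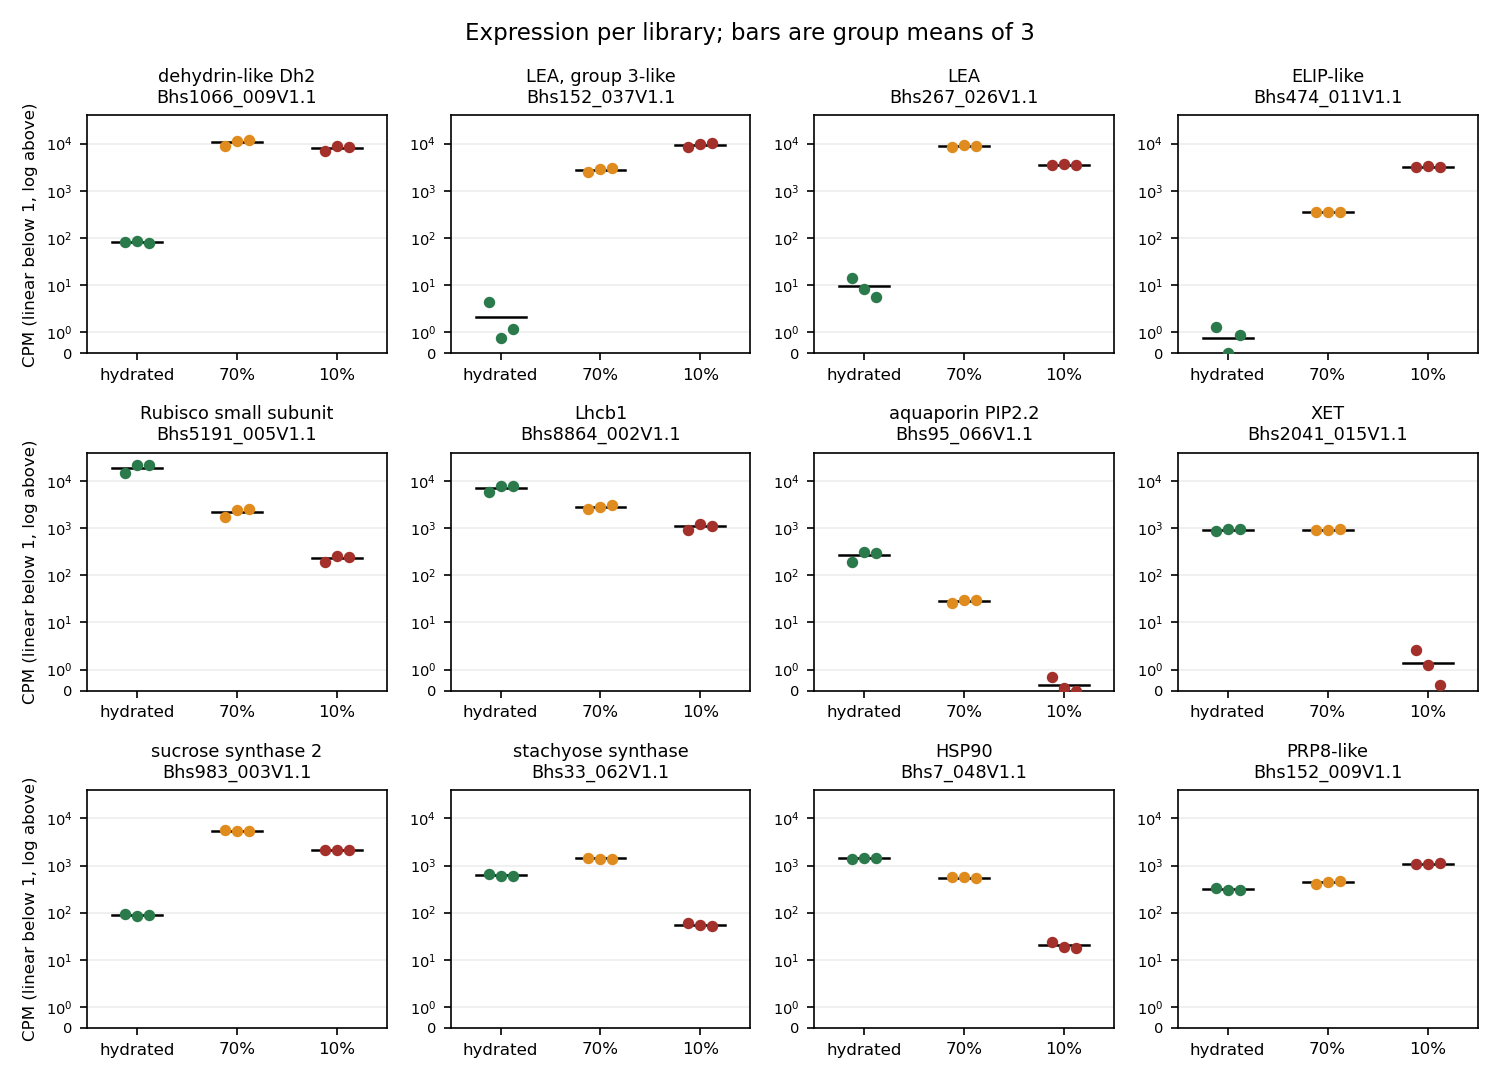
CPM of 12 genes named in the text in each of the 9 libraries (points, replicates 1 to 3 from left to right) with the group mean (bars), on an axis that is linear below 1 CPM and logarithmic above. ELIP Bhs474_011V1.1 and LEA gene Bhs152_037V1.1 were higher at 10% than at 70% RWC, stachyose synthase was higher at 70% and lower at 10% RWC than in hydrated leaves, and XET Bhs2041_015V1.1 was lower at 10% RWC.

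The other lists were not called as sets at 10% RWC. Small heat shock proteins had 2 higher and 7 lower of 10, adjusted p = 0.144, and the mitochondrial member Bhs305_013V1.1 fell from 289.6 ± 22.3 to 57.5 ± 4.0996 CPM and the larger heat shock protein Bhs29_014V1.1 from 47.3 ± 4.67 to 15.9 ± 2.14 CPM. Without the larger heat shock proteins the list had 2 higher and 3 lower of 5 tested (adjusted p = 0.598, and adjusted p = 0.748 with an estimated correlation). Large heat shock proteins had 8 higher and 19 lower of 34, adjusted p = 0.0931. HSP90 Bhs7_048V1.1 fell from 1417 ± 38.5 to 20.2 ± 3.35 CPM and a chloroplast HSP70 gene, Bhs126_016V1.1, from 1067 ± 54.2 to 417 ± 25.98 CPM. Oleosins and seed storage proteins had 6 higher and 4 lower of 10, adjusted p = 0.353. Globulin Bhs83_038V1.1 rose from 266 ± 45.5 to 866 ± 144 CPM and the peroxygenase from 32.6 ± 0.989998 to 525 ± 8.95 CPM. Raffinose family and sucrose synthesis had 11 higher and 11 lower of 25, adjusted p = 0.781. Sucrose synthase 2 rose from 88.3 ± 3.08 to 2152 ± 25.3 CPM and stachyose synthase fell from 616 ± 44.9 to 56.1 ± 4.65 CPM. Antioxidant enzymes had 12 higher and 25 lower of 47, adjusted p = 0.156. Glutathione peroxidase Bhs4_048V1.1 rose from 84.96 ± 8.08 to 755 ± 19.1 CPM and manganese superoxide dismutase (Bhs109_028V1.1) fell from 227 ± 12.4 to 51.9 ± 4.23 CPM. Glutathione S-transferases had 5 higher and 10 lower of 16, adjusted p = 0.197. Bhs63_020V1.1 rose from 283 ± 3.17 to 1257 ± 76.7 CPM and the theta-class gene Bhs700_081V1.1 fell from 131 ± 2.599 to 34.2 ± 1.02 CPM. Chlorophyll breakdown had 6 higher and 3 lower of 9, adjusted p = 0.1703. Bhs7_151V1.1 rose from 11.9 ± 1.28 to 577 ± 12.1 CPM and a stay-green gene, Bhs427_016V1.1, from 38.4 ± 0.688 to 379 ± 36.2 CPM. Lipid remodelling had 22 higher and 14 lower of 43, adjusted p = 0.573, with a median of 0.23, a mean of -0.21 and a positive set test. Phospholipase D Bhs3997_016V1.1 rose from 46.5 ± 4.69 to 390.5 ± 5.14 CPM, and lipoxygenase Bhs2748_005V1.1 fell from 354 ± 11.1 to 11.8 ± 1.73 CPM. Actin and tubulin had 13 higher and 15 lower of 30, adjusted p = 0.179, and without actin-binding and actin-related proteins 3 higher and 11 lower of 14 tested (adjusted p = 0.003004, and adjusted p = 0.0575 with an estimated correlation). Actin 1 fell from 1509 ± 9.83 to 565 ± 17.6 CPM and alpha tubulin Bhs12_047V1.1 from 1450.4 ± 38.8 to 185 ± 5.89 CPM.

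NAC factors at 10% RWC had 10 higher and 10 lower of 25, adjusted p = 0.748, with a median of -0.29, a mean of 0.18 and a positive set test. WRKY factors had 16 higher and 14 lower of 36, adjusted p = 0.7202, with a median of 0.28, a mean of -0.57 and a positive set test. AP2/ERF and DREB factors had 20 higher and 28 lower of 52, adjusted p = 0.548, and MYB factors 14 higher and 23 lower of 44, adjusted p = 0.258. WRKY6 rose from 92.9 ± 5.76 to 1159 ± 2.64 CPM and WRKY I from 53.1 ± 4.23 to 286 ± 7.65 CPM. NAC gene Bhs574_015V1.1 rose from 28.04 ± 2.39 to 156 ± 5.88 CPM, and the NAC78-like gene fell from 68.6 ± 6.31 to 32.98 ± 1.35 CPM. DREB gene Bhs177_007V1.1 rose from 5.41 ± 0.624 to 258 ± 9.505 CPM, and an AP2/B3 repressor gene, Bhs1907_009V1.1, fell from 102 ± 5.12 to 34.03 ± 0.784 CPM. MYB44 rose from 18.3 ± 2.298 to 190.2 ± 39.4 CPM and MYB-like Bhs3124_004V1.1 from 27.3 ± 1.68 to 66.8 ± 1.89 CPM. Vascular markers had 8 higher and 10 lower of 18, adjusted p = 0.697. The sucrose transporter rose from 48.9 ± 3.52 to 1687 ± 86.6 CPM and laccase Bhs649_092V1.1 from 50.5 ± 2.27 to 1301 ± 138 CPM. All 4 guard cell markers were lower, including MYB60 (20.4 ± 2.803 to 0.817 ± 0.356 CPM) and the anion channel SLAC1 (Bhs280_050V1.1, 10.8 ± 0.415 to 3.63 ± 0.965 CPM). Adjusted over the list alone, counts matched those over all genes except in large heat shock proteins (7 higher), histones (16 higher), lipid remodelling (15 lower) and splicing factors (37 higher).

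The third comparison set 10% RWC against 70% RWC, the change from moderate dehydration to desiccation. Genes of the LEA list were mostly lower at 10% RWC, with 19 of 27 members lower and 5 higher, and their share went from 6.72 ± 0.794% to 3.42 ± 0.386% of all CPM. ELIPs moved the other way, with 10 of 13 higher and 3 lower, and Bhs474_011V1.1 rose from 357 ± 8.02 to 3244 ± 83.5 CPM. Splicing factors were higher for 36 of 50 members and lower for 4. XET Bhs2041_015V1.1 fell from 919 ± 19.1 to 1.398 ± 1.202 CPM (log2 fold change -9.33 ± 0.23, adjusted p = 6.43e-12). HSP90 fell from 554 ± 19.8 to 20.2 ± 3.35 CPM (log2 fold change -4.77 ± 0.09).

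In total 11194 of 14585 genes differed by edgeR's quasi-likelihood test, 5415 higher and 5779 lower at 10% RWC, and 6355 differed at least 2-fold (2712 higher, 3643 lower). Total-count scaling turned the balance to 5755 higher and 5438 lower, while RLE scaling gave 5284 and 5919 and DESeq2 5141 and 5749. Replicates 2 and 3 alone gave 11363 genes, and their log2 fold changes and those of replicate 1 had r = 0.961 across all 14585 genes.

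The largest increases from 70% to 10% RWC were in a subtilase, a protease gene (Bhs4312_001V1.1, 0.391 ± 0.369 to 44.2 ± 3.32 CPM), and a YUCCA6-like monooxygenase gene (Bhs4_011V1.1, 0.293 ± 0.387 to 26.7 ± 1.18 CPM). The vacuolar exchanger Bhs370_036V1.1 rose from 0.729 ± 0.398 to 40.8 ± 1.59 CPM, laccase-14 (Bhs649_091V1.1) from 0.765 ± 0.284 to 37.8 ± 4.65 CPM, ELIP Bhs2978_003V1.1 from 6.48 ± 2.12 to 301 ± 29.2 CPM and glucosyltransferase Bhs672_026V1.1 from 16.4 ± 1.22 to 737 ± 33.6 CPM. The largest decreases, after XET Bhs2041_015V1.1, began with a carotenoid cleavage dioxygenase gene, Bhs358_004V1.1, which fell from 35.1 ± 3.59 to 0.0467 ± 0.08096 CPM, a read ratio of 0.001297 with a counting interval of 3.28e-05 to 0.00725. UDP-glucosyltransferase Bhs8667_001V1.1 fell from 30.3 ± 1.404 to 0.0444 ± 0.0769 CPM, a read ratio of 0.001499 with a counting interval of 3.79e-05 to 0.00838. A DREB gene, Bhs4995_001V1.1, fell from 50.1 ± 2.85 to 0.0901 ± 0.156 CPM, a read ratio of 0.00181 with a counting interval of 2.19e-04 to 0.00657. An ankyrin repeat gene, Bhs1646_003V1.1, fell from 84.5 ± 6.26 to 0.355 ± 0.615 CPM and germin-like Bhs7066_001V1.1 from 306 ± 53.4 to 1.41 ± 0.0772 CPM.

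Camera called 8 lists between 70% and 10% RWC, and with an estimated correlation it called 0, with 7 lists at an unadjusted p under 0.05. LEA proteins were lower (median log2 fold change -1.10, adjusted p = 0.0233, and adjusted p = 0.3997 with an estimated correlation). Bhs267_026V1.1 fell from 8988 ± 403 to 3556 ± 78.3 CPM and Bhs152_037V1.1 rose from 2830.4 ± 285 to 9536 ± 984 CPM. ELIPs were higher (median log2 fold change 3.28, adjusted p = 0.0445, and adjusted p = 0.3997 with an estimated correlation). The ELIP call changed in 4 of 15 settings, with adjusted p from 0.0283 to 0.0595. It was lost with the replicate block (adjusted p = 0.0517), with replicate 1 as a batch (adjusted p = 0.0595) and without replicate 2 or replicate 3 of 10% RWC (adjusted p = 0.0503 and 0.0528). ELIP Bhs9122_001V1.1 rose from 17.4 ± 0.283 to 305 ± 16.3 CPM. Splicing factors were higher (adjusted p = 1.16e-04, and adjusted p = 0.194 with an estimated correlation). PRP8-like Bhs152_009V1.1 rose from 438 ± 24.7 to 1099.6 ± 18.99 CPM and U5 helicase Bhs200_062V1.1 from 296 ± 19.9 to 1105 ± 39.7 CPM. Cell wall genes had 14 higher and 46 lower of 82 tested (adjusted p = 0.0233, and adjusted p = 0.127 with an estimated correlation). Pectinesterase Bhs1456_002V1.1 fell from 1233 ± 197 to 52.7 ± 9.48 CPM. Lipid remodelling had 6 higher and 28 lower of 43 tested (adjusted p = 0.0164, and adjusted p = 0.138 with an estimated correlation). Diacylglycerol kinase fell from 374 ± 26.2 to 62.2 ± 3.24 CPM and lipoxygenase from 78.8 ± 3.52 to 11.8 ± 1.73 CPM. Phenylpropanoid enzymes had 11 higher and 31 lower of 50 tested (adjusted p = 0.0123, and adjusted p = 0.127 with an estimated correlation). Phenylalanine ammonia-lyase fell from 146 ± 11.2 to 7.59 ± 1.97 CPM and the rhamnosyltransferase from 627 ± 36.3 to 36.6 ± 0.703 CPM. Antioxidant enzymes had 6 higher and 25 lower of 47 tested (adjusted p = 0.0241, and adjusted p = 0.138 with an estimated correlation). Glutathione peroxidase fell from 1911 ± 139.7 to 755 ± 19.1 CPM and manganese superoxide dismutase from 916 ± 79.98 to 51.9 ± 4.23 CPM. Large heat shock proteins had 8 higher and 19 lower of 34 tested (adjusted p = 0.0372, and adjusted p = 0.406 with an estimated correlation). Luminal-binding protein Bhs78_025V1.1 fell from 564 ± 12.4 to 62.4 ± 3.94 CPM. That call was lost when replicates 2 and 3 were summed (adjusted p = 0.0574, from 0.0188 to 0.0574 over 15 settings) and without co-chaperones and interacting proteins (adjusted p = 0.0671, and adjusted p = 0.327 with an estimated correlation).

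Photosystems had 7 higher and 19 lower of 30, adjusted p = 0.0651, with adjusted p from 0.0178 to 0.0809 over 15 settings. With the replicate block the list was called lower (adjusted p = 0.0186), as with replicate 1 as a batch (adjusted p = 0.0185), in replicates 2 and 3 alone (adjusted p = 0.0178), with total-count scaling (adjusted p = 0.0493) and without replicate 1 of hydrated leaves or of 70% RWC (adjusted p = 0.0425 and 0.0423). It was not called with replicates 2 and 3 summed (adjusted p = 0.0704) or with an estimated correlation (adjusted p = 0.537). Without the ELIPs among its members it had 3 higher and 19 lower of 26 tested (adjusted p = 0.00584, and adjusted p = 0.351 with an estimated correlation). Lhcb1 fell from 2809.9 ± 253 to 1090.3 ± 143 CPM and a chlorophyll a/b binding protein gene, Bhs1817_007V1.1, from 782 ± 153 to 205 ± 34.6 CPM. Calvin cycle had 6 higher and 12 lower of 23, adjusted p = 0.163, and without chaperonins and methyltransferases 0 higher and 9 lower of 9 tested (adjusted p = 9.60e-04, and adjusted p = 0.107 with an estimated correlation). The Rubisco small subunit fell from 2209 ± 454 to 232 ± 33.9 CPM and activase Bhs7545_001V1.1 from 1228 ± 105 to 449 ± 37.2 CPM. Chlorophyll synthesis had 3 higher and 4 lower of 9, adjusted p = 0.6595. Magnesium chelatase fell from 289 ± 5.36 to 52.6 ± 5.38 CPM and geranylgeranyl reductase (Bhs4002_004V1.1) from 75.96 ± 4.72 to 35.7 ± 2.84 CPM. Chlorophyll breakdown had 1 higher and 6 lower of 9, adjusted p = 0.134. A DIN1-like gene, Bhs11213_001V1.1, fell from 47.6 ± 4.55 to 11.1 ± 0.5704 CPM. A stay-green gene, Bhs80_031V1.1, fell from 1.21 ± 0.603 to 0.408 ± 0.01097 CPM, a call lost without replicate 2 of 70% RWC (adjusted p = 0.139, from 0.00995 to 0.139 over 20 alternatives). Cytosolic ribosomal proteins had 16 higher and 44 lower of 87, adjusted p = 0.137. L7-like Bhs33_044V1.1 rose from 123 ± 6.89 to 312 ± 40.2 CPM and L23A (Bhs95_025V1.1) fell from 159.8 ± 3.55 to 63.3 ± 8.66 CPM. Organelle ribosomal proteins had 11 higher and 11 lower of 31, adjusted p = 0.745. S9 (Bhs7_131V1.1) fell from 103 ± 17.2 to 39.5 ± 9.09 CPM and S5 (Bhs8868_003V1.1) rose from 24.8 ± 2.48 to 62.2 ± 4.198 CPM. The proteasome had 14 higher and 10 lower of 32, adjusted p = 0.604. A regulatory subunit, Bhs2753_004V1.1, rose from 35.004 ± 1.29 to 78.9 ± 3.13 CPM and beta subunit Bhs13074_002V1.1 fell from 10.02 ± 1.27 to 2.28 ± 0.887 CPM. Ubiquitin ligases had 99 higher and 74 lower of 218, adjusted p = 0.137. BRE1A-like Bhs710_012V1.1 rose from 440.2 ± 19.6 to 1322 ± 89.5 CPM and UPL4-like Bhs7077_004V1.1 from 306 ± 15.2 to 1386 ± 23.2 CPM. Autophagy had 4 higher and 0 lower of 6, adjusted p = 0.109. ATG9-like Bhs12_112V1.1 rose from 90.6 ± 1.498 to 275 ± 7.33 CPM and ATG5-like Bhs4989_007V1.1 from 44.2 ± 2.11 to 108 ± 3.004 CPM.

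Small heat shock proteins had 2 higher and 6 lower of 10, adjusted p = 0.221, with a median of -1.10. Without the larger heat shock proteins the list had 2 higher and 2 lower of 5 tested (adjusted p = 0.817, and adjusted p = 0.902 with an estimated correlation), and the median turned to 0.70. The mitochondrial member Bhs305_013V1.1 fell from 146 ± 11.6 to 57.5 ± 4.0996 CPM and the larger heat shock protein Bhs3177_005V1.1 from 587 ± 18.4 to 188 ± 6.33 CPM. Oleosins and seed storage proteins had 3 higher and 3 lower of 10, adjusted p = 0.745, and their median of -0.02 became 0.05 with total-count scaling. Without globulins and antimicrobial peptides the list had 0 higher and 1 lower of 3 tested. The peroxygenase fell from 1264 ± 35.97 to 525 ± 8.95 CPM and globulin Bhs98_031V1.1 from 249.9 ± 46.8 to 64.01 ± 11.97 CPM. Raffinose family and sucrose synthesis had 6 higher and 12 lower of 25, adjusted p = 0.134. Sucrose synthase 2 fell from 5508 ± 52.6 to 2152 ± 25.3 CPM and stachyose synthase from 1409 ± 56.9 to 56.1 ± 4.65 CPM. Glutathione S-transferases had 3 higher and 10 lower of 16, adjusted p = 0.109. Bhs63_020V1.1 rose from 390.4 ± 11.6 to 1257 ± 76.7 CPM and the omega-class gene Bhs95_036V1.1 fell from 203 ± 5.33 to 83.9 ± 2.88 CPM. The ABA list had 17 higher and 23 lower of 48, adjusted p = 0.481. Phosphatase 2C Bhs71_001V1.1 fell from 527 ± 16.5 to 81.9 ± 1.36 CPM and Bhs862_005V1.1 rose from 119 ± 8.66 to 449 ± 18.3 CPM. Histones and cell cycle had 16 higher and 33 lower of 67, adjusted p = 0.184. The kinase Bhs828_018V1.1 rose from 185 ± 2.51 to 510.0 ± 17.7 CPM and histone H1 fell from 279 ± 17.3 to 26.4 ± 1.4004 CPM. Aquaporins had 2 higher and 5 lower of 8, adjusted p = 0.221. Bhs3276_001V1.1 fell from 469 ± 44.4 to 134 ± 17.97 CPM and PIP2.2 from 28.2 ± 2.22 to 0.269 ± 0.351 CPM. Actin and tubulin had 10 higher and 13 lower of 30, adjusted p = 0.547, and their median of -0.06 became 0.02 with total-count scaling. Without actin-binding and actin-related proteins the list had 3 higher and 8 lower of 14 tested (adjusted p = 0.0955, and adjusted p = 0.256 with an estimated correlation), with a median of -0.96. Alpha tubulin Bhs4952_004V1.1 fell from 493 ± 22.6 to 245 ± 6.41 CPM and Bhs2176_005V1.1 from 40.1 ± 5.28 to 8.02 ± 0.341 CPM.

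Heat stress transcription factors had 6 higher and 8 lower of 18, adjusted p = 0.976. The A-6b-like factor fell from 632 ± 42.02 to 77.1 ± 11.8 CPM and factor A3 (Bhs49_049V1.1) rose from 7.83 ± 1.495 to 129.9 ± 9.52 CPM. NAC factors had 8 higher and 11 lower of 25, adjusted p = 0.976. Bhs574_015V1.1 rose from 64.03 ± 5.97 to 156 ± 5.88 CPM and Bhs1_125V1.1 from 17.9 ± 1.42 to 80.5 ± 6.95 CPM. WRKY factors had 13 higher and 17 lower of 36, adjusted p = 0.604. WRKY6 rose from 436 ± 23.3 to 1159 ± 2.64 CPM and Bhs30_046V1.1 from 83.9 ± 2.94 to 211 ± 2.097 CPM. AP2/ERF and DREB factors had 17 higher and 27 lower of 52, adjusted p = 0.265. DREB gene Bhs177_007V1.1 rose from 116 ± 2.06 to 258 ± 9.505 CPM and the AP2/B3 repressor fell from 172 ± 3.36 to 34.03 ± 0.784 CPM. MYB factors had 14 higher and 21 lower of 44, adjusted p = 0.6595. MYB185 rose from 66.3 ± 11.1 to 156 ± 17.9 CPM and MYB330 (Bhs119_009V1.1) from 30.6 ± 2.39 to 83.6 ± 4.69 CPM. Vascular markers had 5 higher and 9 lower of 18, adjusted p = 0.745. Laccase Bhs649_092V1.1 rose from 458 ± 50.02 to 1301 ± 138 CPM and a fasciclin-like protein gene, Bhs11391_001V1.1, fell from 4.82 ± 1.34 to 0.314 ± 0.1999 CPM. Cuticle markers had 5 higher and 18 lower of 32, adjusted p = 0.0762. 3-ketoacyl-CoA synthases Bhs4608_002V1.1 fell from 4.42 ± 0.316 to 0.356 ± 0.504 CPM and Bhs4383_003V1.1 from 47.1 ± 2.22 to 8.23 ± 2.35 CPM. Of the 4 guard cell markers 1 was higher and 3 were lower, among them MYB60 (7.24 ± 1.18 to 0.817 ± 0.356 CPM). Adjusted over the list alone, counts matched those over all genes except in large heat shock proteins (20 lower), histones (32 lower) and ubiquitin ligases (75 lower).

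The comparisons against hydrated leaves shared 7698 genes called in the same direction at 70% and at 10% RWC, 3608 higher and 4090 lower. LEA gene Bhs222_060V1.1, ELIP Bhs474_011V1.1, Lhcb1 and Rubisco activase Bhs7545_001V1.1 were among them. Independent lists of the same sizes would share 4313 genes (2136 higher and 2177 lower), and unchanged groups simulated against the same hydrated libraries shared 0 genes in each of 20 simulations. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.742, beside 0.501 in the simulations, and their covariance was 3.46 beside 0.0171, a difference of 3.44. The 3 hydrated libraries were not split, as 1 of the parts would hold a single library. The simulated covariance of 0.0171 argues against noise of the shared hydrated libraries as the source of most of the excess. A shift common to all 3 hydrated libraries would not show in these simulations. Of the shared genes 1958 rose and 2408 fell again between 70% and 10% RWC, while 871 higher genes moved lower and 457 lower genes moved higher in that step.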

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

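The tests of coding length, coverage breadth and LEA scaling were chosen only after the results had been seen, and so were the example genes of opposite direction.

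Against hydrated leaves, 1389 genes changed in opposite directions at 70% and at 10% RWC, with 776 higher and then lower and 613 lower and then higher. Both changes were at least 2-fold for 230 genes. The WRKY30 gene Bhs3559_008V1.1 went from 14.3 ± 3.13 CPM in hydrated leaves to 127 ± 6.97 at 70% and 0.630 ± 0.377 at 10% RWC (SD, n = 3). A respiratory burst oxidase gene, Bhs4382_010V1.1, whose enzyme family makes superoxide, went from 10.5 ± 1.07 to 48.7 ± 3.09 and 0.995 ± 0.329 CPM. The xyloglucan endotransglucosylase gene XTH7 (Bhs280_024V1.1) went from 13.04 ± 3.13 to 168 ± 4.26 and 3.12 ± 1.39 CPM, and the calcium-dependent kinase gene CDPK1 (Bhs1309_005V1.1) from 11.4 ± 0.493 to 53.2 ± 3.89 and 2.76 ± 0.328 CPM. The subtilase gene Bhs4312_001V1.1 moved the other way, from 7.33 ± 1.62 to 0.391 ± 0.369 and 44.2 ± 3.32 CPM.

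Replicate 1 deviated from replicates 2 and 3 in the same direction in the 3 states, with 2970 genes called between them and a biological coefficient of variation that went from 0.0769 to 0.0358 once replicate 1 was a batch term. Coding length bias is argued against, as the deviation and log2 coding length had rho = 0.112 across genes. A different water state of the replicate 1 plants is argued against as well, since the deviation and the change from hydrated to 10% RWC had r = 0.0472 across genes. The coverage breadth of replicate 1, relative to that expected at random, lay outside that of both other replicates in 1 of 3 states. Lower RNA integrity called for all 3 states, so its prediction was not met. In hydrated leaves the breadth of replicate 1 was 0.871 against 0.88009 and 0.882, while at 70% and at 10% RWC it lay between those of replicates 2 and 3. Breadth is an indirect measure of integrity, so lower RNA integrity is not settled by it. A different day, sequencing run or set of plants may also be the source and was not tested, as the labels name none.

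LEA genes were lower at 10% than at 70% RWC, with 19 of 27 lower and a median log2 change of -1.10, a call lost with an estimated correlation (adjusted p = 0.400). Replicates 2 and 3 alone gave -1.04, which argues against a deviation of replicate 1 in 1 of the states alone. A gap shared by the states cancels in this comparison by design, as each state held 1 replicate 1 library, so the value does not test it. Competition among a few very abundant members is argued against too, as 68.2% of the members outside the 5 most abundant were called lower. The scaling of the libraries stays open. The median was -1.02 at its closest to 0 under RLE or total-count scaling, but these move the median of all genes by only -0.0321 and 0.0767, too little to reach 0. A lower transcript level in desiccated than in moderately dry leaves also stays open, and reads shared between near-identical copies were not tested.

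With 3 against 3 libraries 10 splits exist, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many genes were called, and the real splits gave 10102 genes at 70% RWC, 12077 at 10% RWC and 10750 between 70% and 10% RWC when fitted on the 6 libraries. The highest other split gave 0 genes in each comparison by edgeR and 0 by limma-voom, with 102, 22 and 42 genes at an unadjusted p under 0.05. The other 3 splits that part 3 same-numbered pairs gave 0 genes by edgeR as well, with at most 29, 4 and 6 genes at that unadjusted p. All splits but the real one put libraries of both states in each group, so the state difference widened the spread within groups. Few calls were thus set in advance, and these splits do not show what chance alone would give.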

How the results depend on the processing

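Fits on replicates 2 and 3 alone, on their sum, with replicate 1 as a batch term and without unrelated list members were chosen after the data had been seen. Genes called at 70% RWC ranged from 9142 to 10986 over settings other than the 2-fold minimum, at 10% RWC from 10685 to 13646 and between 70% and 10% RWC from 9987 to 11887, with 6778 to 8217 shared between 70% and 10% RWC. With a minimum of 2-fold, 5189, 8116 and 6355 genes were called and 3887 were shared. Without each library in turn the counts were 9843 to 10495, 12038 to 12493 and 10841 to 11482, with 7342 to 7755 shared. The replicate block gave 10928, 12621 and 11728 genes, with 8177 shared, and no called gene changed direction in any setting.

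Lists called numbered 18, 18 and 8, and 17 to 18, 17 to 18 and 7 to 9 without each library in turn. With an estimated correlation camera called 7, 6 and 0 lists (14, 11 and 7 at an unadjusted p under 0.05), and fry, which asks whether a list moves at all, called 29, 28 and 29. Fry's direction differed from camera's for small and large heat shock proteins at 70% RWC and for heat stress and NAC factors between 70% and 10% RWC, none of them called by camera. Beyond the list calls given beside their results, the block changed no other call. Without unrelated members 19, 19 and 9 lists were called. Medians of uncalled lists also changed sign with the replicates used, in NAC factors and raffinose at 10% RWC, small and large heat shock proteins at 70% RWC, and oleosins, NAC factors and the proteasome between 70% and 10% RWC. Of 5079 values of named genes under the alternatives, 5071 stayed on their side of the threshold, 8 lost the call, 7 of them of Bhs2912_005V1.1 and 1 of Bhs80_031V1.1, and 0 reversed. The cause was not tested. With counts thinned to the smallest library, Bhs2912_005V1.1 lost the call (adjusted p = 0.0557, from 0.00727 to 0.152 over 21 alternatives), while Bhs80_031V1.1 kept it. Total-count scaling moved the median of all genes by -0.10 at 70% RWC, no filter by -0.10 and a fit of the 2 states by -0.12 at 10% RWC, and leaving out replicate 1 of 70% RWC by -0.11 at 10% RWC against both other states.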

Other observations

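The gene ontology terms below were tested, and the abundant genes chosen, only after the values had been seen, and in the test of genes without a match the rule for reading the sign of the difference was set after a first look.

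Extracellular region genes were lower for 95 of 141 and higher for 23 at 70% RWC (adjusted p = 3.19e-06). At 10% RWC 105 were lower and 24 higher (adjusted p = 1.95e-07). Photosystem II genes were lower for 16 of 17 at 10% RWC (adjusted p = 0.000182). Proteasome regulatory particle genes were higher for 15 of 15 at 10% RWC (adjusted p = 0.00288). Cullin-RING ubiquitin ligase complex genes were higher for 59 of 82 and lower for 8 at 10% RWC (adjusted p = 0.000458). Unlike the fixed antioxidant list, antioxidant activity genes were lower for 27 of 37 and higher for 6 at 70% RWC (adjusted p = 0.0179). At 10% RWC 31 were lower and 3 higher (adjusted p = 0.000182). With an estimated correlation, adjusted p was 0.0587 to 0.376. Of 457 terms, camera called 12 higher and 27 lower at 70% RWC, 8 and 31 at 10% RWC, and 7 and 23 between 70% and 10% RWC. With an estimated correlation it called 0 terms in each, with 46, 62 and 55 terms at an unadjusted p under 0.05.

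The genes below were among the 5 most abundant in at least 1 state (mean ± SD, n = 3). Galactinol synthase 2 (Bhs17782_001V1.1), which makes the galactosyl donor for raffinose, stood at 8916 ± 388 CPM in hydrated leaves, 5681 ± 272 at 70% and 6009 ± 321 at 10% RWC. A gene without an informative description, Bhs558_007V1.1, went from 44.2 ± 2.57 to 12485 ± 681 and 8815 ± 404 CPM. The gene bdn1 (Bhs1119_057V1.1) went from 5803 ± 746 to 10153 ± 226 and 2302 ± 130.4 CPM, and glycine-rich protein 1 (Bhs4783_003V1.1) from 5184 ± 309.6 to 10068 ± 282 and 9756 ± 617 CPM. Another gene of unknown function, Bhs784_020V1.1, fell from 5019.8 ± 336 to 1469 ± 74.3 CPM at 70% RWC and stood at 7888 ± 503 CPM at 10% RWC. The 10 most abundant genes of a library held 10.3 ± 0.849% of reads in hydrated leaves, 9.37 ± 0.461% at 70% and 7.73 ± 0.287% at 10% RWC.

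Genes without a database match changed at least 4-fold at 10% RWC more often than genes with one (40.05% of 442 against 28.997% of 14143, a difference of 11.05 percentage points). Lower expression may account for the excess, since among genes matched on mean log2 CPM the difference was -7.01 points (bootstrap SD 2.54). Matching on coding length as well gave -2.03 points (SD 2.79), which does not bear on coding length, since matching on level had already removed the excess. Shorter coding length stays open.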
